A study of Homo sapiens with 6 samples.

How the data were processed

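RNA was sequenced from 6 libraries of THP-1 cells, a human monocytic leukaemia line. Per the labels' protocols, the cells were turned into macrophage-like cells (M0) with 100 ng/ml of the phorbol ester PMA, and the titles add CSE for 48 h. The labels do not spell out CSE; in work on chronic obstructive pulmonary disease (COPD) it usually stands for cigarette smoke extract. The 3 control libraries carried a control siRNA (si-NC) and the 3 others an siRNA against CLEC5A (si-CLEC5A). Groups were taken from the titles, because the genotype labels of the 3 knockdown libraries count up from CLEC5A to CLEC6A and CLEC7A while every title and description of theirs names CLEC5A. The extraction text mentions lung tissue beside cells, so markers of lung cell types were looked at as well.

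The authors deposited a table of whole-number read counts per Ensembl gene and a table of TPM values (transcripts per 1000000) for the same 35428 genes and 6 libraries. Per the submitters' processing notes, HISAT2, Subread, featureCounts, DESeq2 and edgeR were used and the genome build was hg38. Versions, the annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Reads from a gene and its antisense partner, and from near-identical copies such as CCL3 and CCL3L3 or CCL4 and CCL4L2, therefore cannot be told apart with certainty. The deposited TPM columns each summed to 1000000. For the 11203 genes with more than 50 counts in every library, counts divided by TPM gave the same gene length in each library up to 1 factor per library, to within a relative deviation of 1e-06. The TPM values thus hold the same information as the counts, scaled by gene length.

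Total counts per library lay between 17488281 and 20900425. Counting error is small for abundant genes at this depth and large for scarce ones such as CLEC5A. No 2 libraries agreed within sampling noise, the lowest chi-square per degree of freedom being 3.26, so each was counted as 1 replicate. No label says that the 3 libraries of a group came from separate cultures. The p-values then measure only the spread between these samples, which may be technical.

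The comparison of si-CLEC5A with si-NC was fitted to the counts with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, glmQLFit and glmQLFTest, TMM scaling, no covariate). The filter was filterByExpr with its defaults, a minimum count of 10 and a minimum total of 15, which left 16506 genes. Adjusted p-values follow Benjamini and Hochberg, and a gene was called at an adjusted p under 0.05. A second count took only called genes with a change of at least 2-fold. CPM values are TMM-scaled counts per 1000000, given as mean ± SD over 3 libraries, and standard errors of log2 fold changes come from the quasi-F statistic. Shares of counts were compared with an exact two-sided permutation test, which with 3 libraries against 3 cannot go below 0.1.

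Gene lists, 35 in all, were fixed before the data were examined, together with the tests, the alternatives and the rule for named genes. They cover CLEC5A signalling, lectin receptors, inflammation, smoke and stress responses, metabolism, macrophage state, RNA quality and other cell types. The 33 lists with at least 5 tested members were tested with camera in limma 3.58.1, with its preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 33 lists. Camera with an estimated correlation and fry were run beside it. Of the 748 distinct genes on the lists, 618 were tested.

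The rule for named genes took CLEC5A, CLEC6A and CLEC7A first. It then took the 8 largest rises and the 8 largest falls among called genes with a symbol, a mean of at least 1 CPM and no overlap between the groups. From each main list up to 3 members followed, and from each other list up to 2, in order of adjusted p, or the most abundant members where fewer than 2 passed. Some genes named outside the rule are said to be so. Others, such as CCL5, TNF and MMP9, are named as members of their lists without that remark. The CLEC5A signalling list's count adjusted over the list alone is not reported here. CLEC6A was not analysed here. Symbols came from a current gene name table, which named 35360 of the 35428 identifiers, and from GENCODE 29 for 62 more. Coordinates are those of GENCODE 29 on GRCh38, the build called hg38 in the notes; that release holds 95.2% of the identifiers.

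The test was checked on counts simulated from the real means, dispersions and library sizes, with 200 genes changed. At a simulated 1.5-fold change edgeR recovered 44% of the changed genes, at 2-fold 80%, at 3-fold 94% and at 4-fold 96%, over 16084 genes tested, and 8.72% of its calls were false. A second simulation added a trend in GC content to 1 library and gave all genes the same dispersion, set well below the real median. There, recovery at 1.5-fold was 6%, and 84% once the trend had been removed. Because of the smaller dispersion, these shares cannot be set beside the 44% and do not give the recovery at the spread of these data.

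Alternatives covered the scaling, the filter on low counts, DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1) and log2(TPM + 0.1), the replicate number as a block, and each library left out in turn. After the data had been seen, fits with smooth trends in GC content and gene length removed from each library were added (splines with 5 degrees of freedom). GC content is that of the longest GENCODE 29 transcript, known for 98.01% of tested genes, and gene length is the one implied by the 2 tables. Every column of the 2 tables was used.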

Results

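The series asks what CLEC5A does in macrophages under a stimulus used in COPD research. CLEC5A is a C-type lectin receptor of myeloid cells that signals through the adaptor TYROBP. RNA-seq counts were available for 3 libraries of PMA-differentiated THP-1 cells with CSE and control siRNA (si-NC) and 3 with CSE and siRNA against CLEC5A (si-CLEC5A). The si-NC libraries held 17488281, 19695738 and 18820066 counts, and the si-CLEC5A libraries 20900425, 19893886 and 17848728. There was no library without CSE, so the response to CSE itself was not measured. The p-values measure only the spread between these samples, which may be technical, since no label says that replicates were separate cultures.

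CLEC5A mRNA was low in both groups and lower in each si-CLEC5A library than in any si-NC library. The gene (ENSG00000258227, protein coding) lies on the minus strand of chromosome 7, from 141927357 to 141947007 in hg38. It had 28, 71 and 27 counts in si-NC replicates 1, 2 and 3, against 4, 9 and 11 in si-CLEC5A. The mean level was 2.21 ± 1.17 CPM (SD, n = 3) in si-NC and 0.421 ± 0.215 CPM in si-CLEC5A, which in the authors' deposited TPM was 2.05 ± 1.12 against 0.402 ± 0.205. The fitted difference was 5.29-fold, a log2 fold change of -2.40 (SE 0.53). Over all genes it did not pass, at an edgeR adjusted p of 0.0817 (unadjusted 0.000483), and the exact permutation test of the CPM values gave 0.1, the smallest p that 3 against 3 libraries allow. Adjusted over the list alone, among the 15 tested genes of CLEC5A signalling, the edgeR p was 0.00725. The gene overlaps MGAM on the other strand, which had 43 counts over the 6 libraries. CLEC7A, which 1 genotype label names, stood at 6.38 ± 0.80 CPM in si-NC and 6.38 ± 1.11 CPM in si-CLEC5A, an edgeR adjusted p of 0.999.

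**Figure D1:**
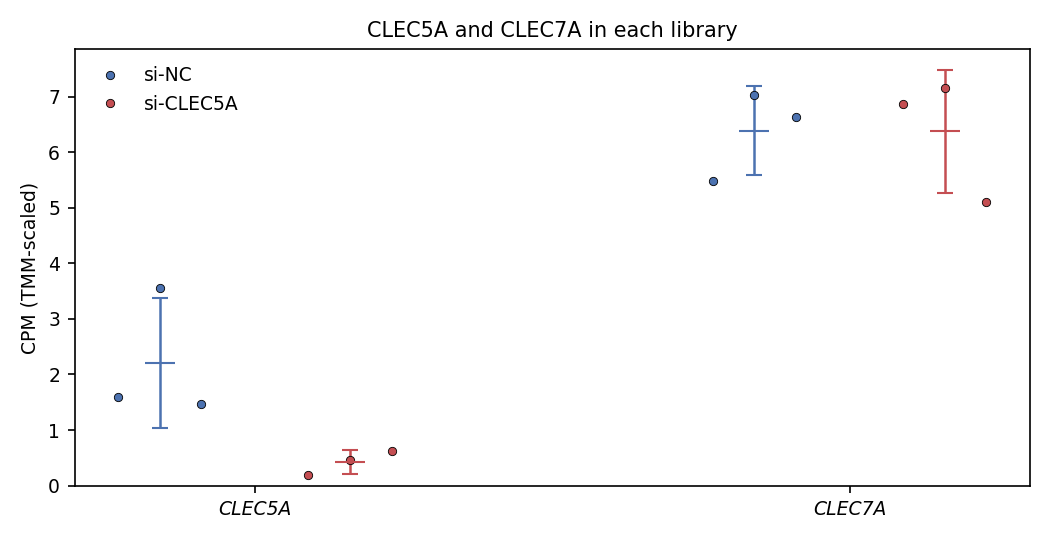
CPM (TMM-scaled, linear axis) of CLEC5A and CLEC7A in each library, with si-NC in blue and si-CLEC5A in red; points are libraries, and bars give the mean and SD of 3 libraries. CLEC5A lies between 1.47 and 3.56 CPM in si-NC and between 0.191 and 0.617 CPM in si-CLEC5A, while the CLEC7A values of the groups overlap.

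Across all genes, the genes called lower in knockdown cells included chemokines, IL1B and 3 matrix metalloproteinases, and those called higher included interferon-inducible genes. Of 16506 genes tested, 47 were called by edgeR, 34 lower and 13 higher in si-CLEC5A, and 16 of them differed at least 2-fold, 14 lower and 2 higher. Chemokine genes made up 12 of the 34. The common biological coefficient of variation was 15.35%. The number of calls rested on single libraries: it was 380 without si-NC replicate 1, 561 without si-NC replicate 2 and 10 without si-NC replicate 3, and 11, 5 and 4 without si-CLEC5A replicates 1, 2 and 3. CXCL5, CXCL8, CCL20 and CCL4L2, 4 genes, were called whichever library was left out. With trends in GC content and gene length removed, a choice made after the data had been seen, 967 genes were called (447 higher, 520 lower), the 47 among them.

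Most of the deepest falls among called genes were in ligands that attract leukocytes. CXCL5, a neutrophil attractant, fell from 12.2 ± 2.7 CPM (SD, n = 3) to 2.55 ± 0.85 CPM, a log2 fold change of -2.25 (SE 0.25) at an edgeR adjusted p of 0.00217. CXCL8, which encodes interleukin 8 and was by far the most abundant of these ligands, fell from 6349 ± 1652 CPM to 2410 ± 129 CPM, 2.63-fold, with the same adjusted p. CCL20, the ligand of CCR6, fell from 225.3 ± 72.4 CPM to 75.7 ± 5.6 CPM, 2.97-fold. CCL4 fell 2.72-fold, from 12.5 ± 2.7 CPM to 4.61 ± 0.65 CPM (edgeR adjusted p = 0.0123). PPBP, the precursor of a platelet and monocyte chemokine, fell from 32.4 ± 10.6 CPM to 12.9 ± 2.0 CPM, a log2 fold change of -1.32 (SE 0.21; edgeR adjusted p = 0.0164).

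Of the 19 tested members of the chemokine list, 9 fell and 0 rose, both over all genes and adjusted over the list alone. Besides CXCL5, CXCL8, CCL20 and CCL4 these were CXCL1, CXCL2, CXCL3, CXCL6 and CCL3, with falls of 1.71-fold for CXCL3 to 2.08-fold for CXCL6. The other 10 did not pass. CCL5 stood at 217.5 CPM in si-NC and 286.1 CPM in si-CLEC5A (log2 fold change 0.40, SE 0.19, edgeR adjusted p = 0.382), and CCL2 at 6.72 and 6.13 CPM. The list as a whole was lower in the camera test, with a median log2 fold change of -0.46 and an adjusted p of 1.69e-05; the adjusted p was 0.466 with an estimated correlation. The median was -0.28 without si-NC replicate 1 and -0.72 without si-NC replicate 2. The called ligands sit in few places of the genome. CXCL1, CXCL2, CXCL3, CXCL5, CXCL6, CXCL8 and PPBP lie on chromosome 4 between 73740506 and 74099293. CCL3, CCL4 and the near-identical copies CCL3L3 and CCL4L2, whose reads cannot be told apart with certainty, lie on chromosome 17 between 36088256 and 36212878. CXCL8 was highest in si-NC replicate 2, at 7913 CPM against 4622 and 6514 CPM in the other si-NC libraries, and that library was rich in reads from genes of low GC content. The number of chemokines called was 4 without si-NC replicate 3 or si-CLEC5A replicate 1 and 3 without si-CLEC5A replicate 2 or 3; limma on log2(TPM + 1) called 0 of them.

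**Figure D2:**
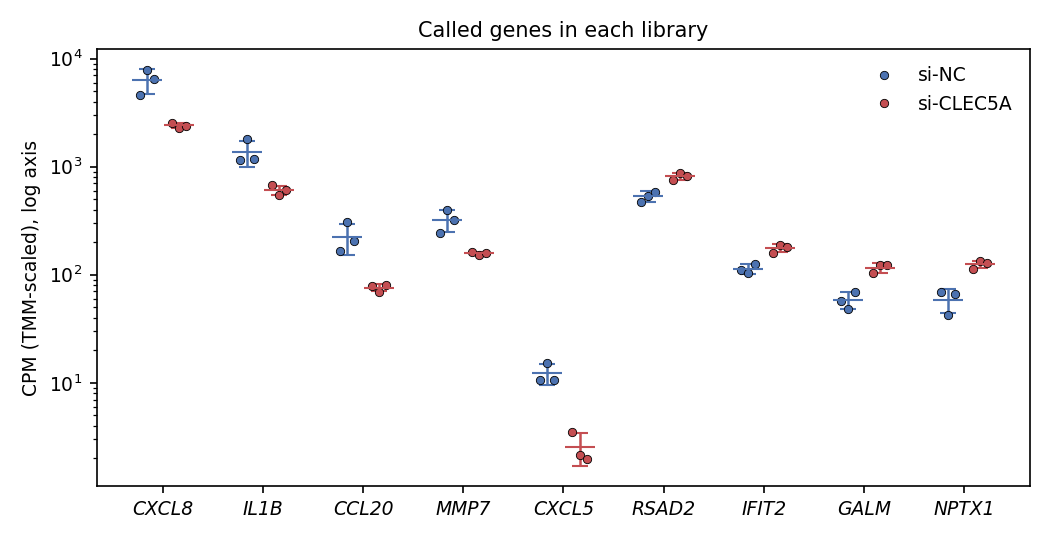
CPM (TMM-scaled, log axis) of 9 called genes in each library, si-NC in blue and si-CLEC5A in red; points are libraries, and bars give the mean and SD of 3 libraries. CXCL8, IL1B, CCL20, MMP7 and CXCL5 lie lower in each si-CLEC5A library, and RSAD2, IFIT2, GALM and NPTX1 higher; CXCL8 spans 4622 to 7913 CPM in si-NC and 2284 to 2541 CPM in si-CLEC5A.

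Other inflammatory mediators were lower too. IL1B, which encodes the cytokine interleukin 1 beta, fell from 1372 ± 372 CPM (SD, n = 3) to 608 ± 60 CPM, 2.26-fold (edgeR adjusted p = 0.0122). SOD2, the mitochondrial superoxide dismutase that NF-kB induces, fell from 515.4 ± 89.5 CPM to 295.5 ± 5.2 CPM, 1.74-fold (edgeR adjusted p = 0.0209). They were the 2 called among the 27 tested NF-kB targets and inflammatory mediators, and adjusted over the list alone 10 were lower and 0 higher. Members that passed only over the list were TNFAIP6, NFKBIA, BIRC3, TNFAIP3, IL1A, IRAK2, IER3 and PTGS2, all outside the naming rule. TNF had a log2 fold change of -0.40 (SE 0.22) and ICAM1 of 0.01 (SE 0.12), and neither passed. The camera test of the list gave a lower level at an adjusted p of 0.000849, and 0.466 with an estimated correlation. IL1B was also the 1 called gene among 17 inflammasome genes (camera adjusted p = 0.412) and among 17 markers of M1-type macrophages (0.231). As lists, both leaned higher, with median log2 fold changes of 0.07 and 0.27 and 10 and 12 of their 17 genes positive. Adjusted over the list alone, 1 inflammasome gene was lower and 0 higher, and 1 M1-type marker was lower and 2 higher. The number of called NF-kB targets was 5 without si-NC replicate 1, 8 without si-NC replicate 2, 1 without si-NC replicate 3 or si-CLEC5A replicate 1, and 0 without si-CLEC5A replicate 2 or 3.

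Several genes that act on the extracellular matrix were lower as well. The collagenase gene MMP8 fell from 36.0 ± 14.6 CPM (SD, n = 3) to 12.2 ± 1.0 CPM, 2.96-fold, and the matrilysin gene MMP7 from 322.2 ± 75.4 CPM to 158.5 ± 5.4 CPM, 2.03-fold, both at an edgeR adjusted p of 0.0123. The stromelysin gene MMP10 fell 2.65-fold, from 7.56 ± 2.45 CPM to 2.84 ± 0.43 CPM (edgeR adjusted p = 0.0463). These genes lie in 1 cluster on chromosome 11, between 102520508 and 102780628. TIMP3, an inhibitor of metalloproteinases, fell 1.50-fold, from 223.9 ± 1.0 CPM to 149.5 ± 5.2 CPM. With SERPINB2, an inhibitor of plasminogen activators, 5 of 29 tested matrix proteases and inhibitors were lower and 0 higher, while adjusted over the list alone 8 were lower and 2 higher. The list did not pass the camera test (median log2 fold change 0.00, mean -0.08, adjusted p = 0.252). It passed as lower with the GC trend removed (adjusted p = 0.0304) and with both trends removed (0.0207, and adjusted p = 0.358 with an estimated correlation). MMP9, at 1783 CPM in si-NC and 1625 CPM in si-CLEC5A, and MMP14, at 4237 and 4457 CPM, did not pass. The number called lower was 8 without si-NC replicate 2, 1 without si-NC replicate 3 or si-CLEC5A replicate 1 and 0 without si-CLEC5A replicate 2 or 3.

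The called rises included genes induced by interferon. RSAD2, which encodes the antiviral enzyme viperin, rose from 531.1 ± 60.5 CPM (SD, n = 3) to 814.8 ± 64.3 CPM, 1.53-fold, and IFIT2 from 113.8 ± 11.8 CPM to 177.2 ± 15.7 CPM, 1.56-fold, at edgeR adjusted p-values of 0.0479 and 0.0463. They were the 2 called of 35 tested type I interferon response genes. Adjusted over the list alone 12 were higher and 0 lower, and 31 of the 35 had a positive log2 fold change, with a median of 0.23. The camera test gave a higher level at an adjusted p of 2.27e-07, and 0.583 with an estimated correlation. Further called genes known to respond to interferon were TNFSF10, which encodes the death ligand TRAIL, with a rise of 1.91-fold from 6.13 ± 0.25 CPM to 11.7 ± 1.4 CPM, GBP4 with 1.76-fold and SERPING1, the complement C1 inhibitor, with 1.67-fold. ZBP1, a sensor of nucleic acids named here after its values were seen because its mean was below 1 CPM, had 6 counts over the si-NC libraries and 89 over the si-CLEC5A libraries (edgeR adjusted p = 0.0396). The number of interferon list members called was 14 without si-NC replicate 2 and 0 without si-NC replicate 3 or any 1 si-CLEC5A library. With a filter of at least 1 CPM in 3 libraries, 0 were called, although both genes were tested.

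The largest rises by the naming rule had no common list. NPTX1, which encodes neuronal pentraxin, rose 2.13-fold from 58.9 ± 14.8 CPM (SD, n = 3) to 125.2 ± 10.0 CPM (edgeR adjusted p = 0.0151). GALM, the mutarotase of galactose metabolism, rose 2.00-fold from 58.4 ± 10.4 CPM to 116.6 ± 12.1 CPM (edgeR adjusted p = 0.0123), and SDS, serine dehydratase, 1.96-fold from 196.2 ± 55.0 CPM to 383.8 ± 41.4 CPM (edgeR adjusted p = 0.0396). The receptor gene EPHB2 rose 1.79-fold and the adenylyl cyclase gene ADCY1 1.59-fold. Among the other falls were SC5D, a sterol desaturase (1.85-fold), and complement C3 (1.52-fold, from 112.0 ± 6.7 CPM to 73.6 ± 4.0 CPM). Outside the naming rule, IL6ST, the shared signalling receptor of interleukin 6 family cytokines, had a log2 fold change of -0.97 (SE 0.15), FCAR, the Fc receptor for IgA, of -0.86 (SE 0.14) and INHBA, the activin subunit, of -0.74 (SE 0.11), each called.

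No cytosolic ribosomal protein gene and no nuclear gene of the respiratory chain on the lists was called over all genes by the main edgeR fit (TMM, filterByExpr, no block). Without si-NC replicate 1 the numbers called lower were 26 and 11, without si-NC replicate 2 they were 28 and 11, and DESeq2 called 20 and 9. With all 6 libraries edgeR called 18 and 11 lower with no filter, and 3 and 3 with the replicate block. With DESeq2's size factors, upper-quartile scaling, limma-voom or a filter of at least 1 or 10 CPM in 3 libraries, 0 of either list were called. Library size alone gave 0 and 1. All 43 tested genes of cytosolic ribosomal proteins had a negative log2 fold change, with a median of -0.42, and 36 were lower adjusted over the list alone. The 30 nuclear genes of the respiratory chain were likewise all negative, with a median of -0.39, and 20 were lower adjusted over the list alone. The camera tests gave adjusted p-values of 5.49e-16 and 1.75e-10, but with an estimated correlation these were 0.618 and 0.583. With GC content and length trends removed, 37 ribosomal protein and 12 respiratory chain genes were called lower. Ribosomal protein mRNAs took 1.277% ± 0.169 (SD, n = 3) of counts in si-NC and 0.988% ± 0.013 in si-CLEC5A, a difference in the same direction for every pair of libraries (exact permutation p = 0.1, the smallest possible). RPL13A stood at 620.5 ± 112.6 CPM against 505.5 ± 28.6 CPM, and ATP5F1B, a subunit of ATP synthase, at 398.1 ± 38.5 CPM against 315.5 ± 7.9 CPM. mRNAs encoded by the mitochondrial genome took 2.449% ± 0.363 of counts in si-NC and 2.278% ± 0.112 in si-CLEC5A (exact permutation p = 0.6), and the camera test of that list did not pass (median log2 fold change -0.13, adjusted p = 0.183). It passed as lower without si-NC replicate 3 (adjusted p = 0.00848) and as higher with GC content and length trends removed (median 0.17, adjusted p = 0.0252, and 0.655 with an estimated correlation).

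Among the 26 tested NRF2 antioxidant genes, which oxidative stress induces, 0 were called over all genes, and 7 were lower and 2 higher adjusted over the list alone. Over all genes 4 were called lower without si-NC replicate 1, and 8 lower and 1 higher without si-NC replicate 2, while DESeq2 called 4 lower and 1 higher. With no filter edgeR called 4 lower and 2 higher. The list was lower in the camera test (adjusted p = 0.0158, and 0.697 with an estimated correlation), but not without si-NC replicate 3 (0.179) or si-CLEC5A replicate 1 (0.0573). Its members went apart: HMOX1, haem oxygenase, had 807 ± 173 CPM (SD, n = 3) in si-NC and 1163 ± 74 CPM in si-CLEC5A, while NQO1, outside the naming rule, had 111.8 and 78.1 CPM. The main edgeR fit called both over the list alone only. HMOX1 passed over all genes in 5 of its 20 alternatives. FTL, the ferritin light chain, had 14665 ± 2315 CPM and 12623 ± 332 CPM and did not pass. Of 16 heat shock genes 0 were called and 4 were lower adjusted over the list alone (camera adjusted p = 0.00886, and 0.583 with an estimated correlation); 2 were called lower without si-NC replicate 1 or 2. Targets of the aryl hydrocarbon receptor, the sensor of aromatic hydrocarbons, did not pass as a list of 7 (camera adjusted p = 0.619), and CYP1B1 had 188.5 and 172.2 CPM.

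Of the 15 tested CLEC5A signalling genes, CLEC5A included, the main edgeR fit called 0 over all genes. With no filter, and with the replicate block, edgeR called 1 lower. The adaptor TYROBP had 890 ± 258 CPM (SD, n = 3) in si-NC and 934 ± 104 CPM in si-CLEC5A, and LYN had 248.7 ± 5.8 and 265.0 ± 12.7 CPM. The list did not pass the camera test (adjusted p = 0.377); its median log2 fold change was 0.02 and its mean -0.23. Of 11 tested C-type lectin receptors the main edgeR fit called 0 (camera adjusted p = 0.693), and of 14 markers of M2-type macrophages also 0 (0.593). Without si-NC replicate 2, 2 of the lectin receptors were called lower and 1 of the M2-type markers higher, and without si-NC replicate 1 also 1 M2-type marker.

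**Figure D3:**
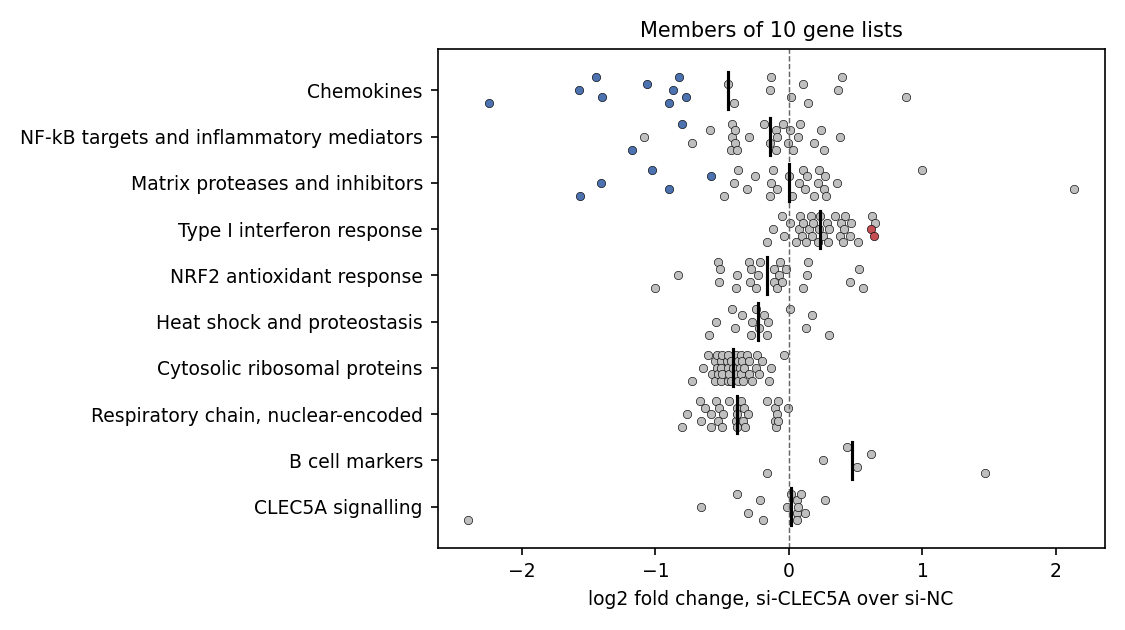
Log2 fold change (si-CLEC5A over si-NC) of the tested members of 10 gene lists; each point is a gene, blue points were called lower, red points called higher, grey points were not called, and black bars are list medians. The 9 called chemokines lie between -2.25 and -0.77, and the 43 ribosomal protein genes all lie below 0 without a call.

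Markers of other cell types were scarce. Fibroblast markers took 0.00143% of counts in si-NC and 0.00145% in si-CLEC5A (exact permutation p = 0.8), epithelial markers 0.00187% and 0.00226% (0.5), T and NK cell markers 0.00652% and 0.00722% (0.3), endothelial markers 0.0153% and 0.0152% (exact permutation p = 1), and erythroid markers had at most 9 counts in a library. B cell markers took 0.00461% ± 0.00074 (SD, n = 3) and 0.00643% ± 0.00040 (exact permutation p = 0.1, the smallest possible). The B cell list was higher in the camera test over 6 tested members (adjusted p = 0.00886, and 0.583 with an estimated correlation), though not without si-CLEC5A replicate 3 (0.0615). CD22 stood at 33.3 and 44.9 CPM and PAX5 at 8.01 and 12.3 CPM, neither called over all genes by the main edgeR fit. CD22 passed over all genes in 2 of its 20 alternatives and PAX5 in 0. The fibroblast, T and NK cell and endothelial lists did not pass (camera adjusted p = 0.405, 0.859 and 0.405), and the epithelial and erythroid lists had only 2 and 0 tested members.

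The control library si-NC replicate 2 stood apart from the other 5. It lay at 34.4 on the first principal component of log2 CPM, which held 64.22% of the variance, while the others lay between -13.4 and 2.56. Across genes, which are not independent replicates, its deviation from the other libraries fell with GC content (Spearman -0.79), so that it held more reads from genes of low GC content. In si-NC replicate 3 the deviation fell with gene length (Spearman -0.38), and in si-CLEC5A replicates 2 and 3 it rose with GC content (0.47 and 0.38). The mean Pearson correlation of si-NC replicate 2 with the other libraries was 0.971, against 0.979 to 0.983 for the rest.

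**Figure D4:**
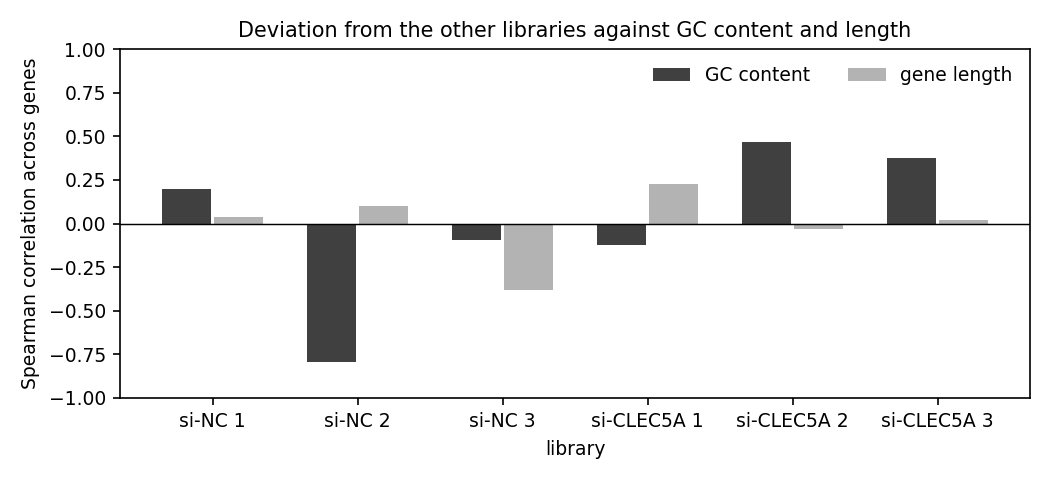
Spearman correlation, across genes, of each library's deviation from the median of the other 5 with GC content (dark bars) and gene length (light bars). The GC bar of si-NC replicate 2 reaches -0.79, and the length bar of si-NC replicate 3 reaches -0.38.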

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

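The fits with GC content or length trends removed, and the list tests combined with them or with a left-out library under an estimated correlation, were chosen after the data had been seen. CLEC5A was lower in each of its 18 alternatives, with log2 fold changes from -2.77 to -1.07 and adjusted p-values from 0.000492 to 0.54; leaving out 1 library gave -2.77 to -1.87. It passed over all genes with no filter (-2.39), with the GC trend removed (-2.25), with both trends removed (-2.24) and with the replicate block (-2.37). The 47 calls, none with overlap between the groups' CPM, kept their direction wherever they were tested, which leaving out a library could hardly change. Their number was 477 with no filter, 469 of them among the genes tested otherwise, 387 with DESeq2 (46 of the 47), 887 with the GC trend removed, 967 with both trends removed, and between 4 and 561 with 1 library left out. limma called 0 genes on log2(TPM + 1), log2(TPM + 0.1) and log2(TPM + 1) of all genes, with 2187, 2162 and 2564 at an unadjusted p under 0.05, against 2286 in edgeR. Calls of at least 2-fold numbered 57, 25, 41 and 44 with no filter, DESeq2, the GC trend and both trends removed, 0 in each limma fit on TPM, and 4 to 40 with 1 library left out. With upper-quartile scaling 45 genes were called, with size factors 46, with library size alone 51, with limma-voom 39. The cause of these differences was not tested.

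Of the gene lists, 8 passed with the preset correlation and 7 to 12 with 1 library left out, but 0 with an estimated correlation (2 at an unadjusted p under 0.05, lowest adjusted p 0.466), 0 with fry (8 unadjusted, lowest adjusted p 0.116), and 0 with an estimated correlation after removal of both trends or without si-NC replicate 2. The list of mitochondrially encoded genes turned from a median of -0.13 to 0.17 with both trends removed (camera adjusted p = 0.0252). With both trends removed the glycolysis and matrix lists passed too, lower, at camera adjusted p-values of 0.000208 and 0.0207, against 0.324 and 0.358 with an estimated correlation. The cause was not tested.

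Between libraries of equal replicate number, the deviations from the group means correlated at -0.331, -0.323 and 0.155 for numbers 1, 2 and 3. The large deviation of si-NC replicate 2 enters all these values, so pairing is neither shown nor excluded. With the replicate block 152 genes were called (67 higher, 85 lower), 33 of them at least 2-fold, the 47 among them, and 8 lists. Depth limits CLEC5A itself, which rests on 24 counts over the si-CLEC5A libraries.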

Other observations

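Chosen only after the result was seen were the tests of near-identical copies, of interferon beta and of whether chemokine calls outlast the removal of trends; so were the fits with trends removed and the genes named in the next paragraph.

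The matrix metalloproteinase cluster on chromosome 11 held genes with log2 fold changes of opposite sign. MMP13 and MMP12, next to the called MMP8, MMP7 and MMP10, had positive log2 fold changes of 2.14 (SE 0.54) and 1.00 (SE 0.32), at 0.312 and 1.72 CPM in si-NC against 1.38 and 3.43 CPM in si-CLEC5A, and passed adjusted over their list alone (edgeR adjusted p = 0.00629 and 0.0274) but not over all genes (0.11 and 0.196). With GC content and length trends removed both passed over all genes, at 0.0233 and 0.0358. That fit also called the tissue factor gene F3 lower (edgeR adjusted p = 0.0244) and ADORA3, an adenosine receptor (1.59, SE 0.30), MNDA, a myeloid nuclear antigen (1.24, SE 0.23), and ACP5, the tartrate-resistant acid phosphatase of macrophages (1.06, SE 0.16), higher.

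The main edgeR fit called no C-type lectin receptor over all genes. Called lower were 2 without si-NC replicate 2, 2 with DESeq2 and 2 with the replicate block, and with no filter 2 were lower and 1 higher. OLR1, the receptor of oxidised LDL, and CLEC2D had log2 fold changes of -0.86 (SE 0.19) and -0.79 (SE 0.18), and MRC2 of 0.48 (SE 0.16). In the main fit these 3 passed adjusted over the list alone. The camera test did not pass the lists of glycolysis and hypoxia (28 genes tested, median -0.14, adjusted p = 0.0652), immediate early genes (25, 0.12, 0.0666), antigen presentation (20, 0.15, 0.125), myeloid precursor genes (10, 0.15, 0.204), the unfolded protein and integrated stress response (25, 0.12, 0.21), lipid handling (22, -0.14, 0.231), sterol synthesis (23, -0.08, 0.245), uptake receptors and complement (20, -0.01, 0.412), PMA-linked macrophage maturation (24, -0.05, 0.619), nuclear non-coding RNAs (7, 0.00, 0.693), the cell cycle (31, 0.00, 0.693), p53 targets (26, 0.00, 0.693), lysosome (29, 0.03, 0.693) and Toll-like receptors (24, 0.02, 0.917). Left-out libraries changed this for immediate early genes (0.0432 without si-NC replicate 1, 0.00834 without si-NC replicate 3, 0.0464 without si-CLEC5A replicate 1) and for glycolysis and hypoxia (0.0021 without si-NC replicate 2, but adjusted p = 0.636 with an estimated correlation). Without si-NC replicate 3 the stress response (0.0179), antigen presentation (0.0298) and myeloid precursor (0.0298) lists passed as well. These values used the preset correlation. For each of these lists and for immediate early genes, camera with an estimated correlation and all 6 libraries gave an adjusted p of 0.719. In the main edgeR fit over all genes, called members of these lists were SC5D for sterol synthesis and C3 for complement. Other fits called more, such as 2 higher and 2 lower among PMA-linked macrophage maturation genes with no filter. B2M, the light chain of MHC class I, stood at 6631 CPM in si-NC and 4891 CPM in si-CLEC5A (log2 fold change -0.44, SE 0.13, edgeR adjusted p = 0.169).

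The first pattern weighed is the fall of the 9 called members of the chemokine list. Their median log2 fold change was -0.857 without library si-NC replicate 2 and -1.06 with it. The 9 were picked by their calls in all 6 libraries, so this alone cannot exclude a part played by that library. Once GC content and length trends were removed, all 9 were still called lower. That fit called 967 genes, all 47 main calls among them, so staying called decides little here. The median of the 9 shrank to -0.792, just short of a bound of 0.75 of its size. The bound was applied to a fit chosen after the data had been seen. A part owed to the trends stays open. Over all 19 tested members, called or not, the median was -0.46 both with and without the trends. This argues against those trends as the whole of the change. The median of the 19 was -0.28 without si-NC replicate 1 and -0.72 without si-NC replicate 2. Reads shared between CCL3, CCL4 and their copies do not account for the whole of it either, as 7 of the 9 are neither CCL3 nor CCL4. Sharing of reads among those 7 was not tested. Lower CLEC5A and an off-target action of the siRNA both stay open, because the labels name no second siRNA.

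The second pattern is the positive log2 fold change of most interferon-stimulated genes, of which 2 of 35 were called and whose list lost its call with an estimated correlation (adjusted p = 0.583) and with fry (0.128). The median of the 35 genes was 0.204 without si-NC replicate 2 and 0.264 with trends removed, against 0.231, which argues against that library and against those trends; with trends removed 19 of the 35 were called higher. A candidate explanation is that cells sensed the CLEC5A siRNA duplex more than the control duplex. Interferon beta mRNA had 3 counts over the 6 libraries, too few to test this, so it cannot be told apart from an effect of lower CLEC5A.

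The third pattern is the negative log2 fold change of ribosomal protein and respiratory chain genes, of which the main edgeR fit called 0 of 73 over all genes. With no filter edgeR called 18 ribosomal protein and 11 respiratory chain genes lower, but 0 of either with at least 1 CPM in 3 libraries. The 73 tested members had a median of -0.393, against -0.349 without si-NC replicate 2 and -0.371 with trends removed. With any 1 library left out, the ribosomal protein median ran from -0.53 to -0.35 and the respiratory chain median from -0.46 to -0.33. The controls were uneven. Ribosomal protein genes took 1.083%, 1.353% and 1.394% of counts in si-NC replicates 1, 2 and 3, against 0.9796% to 1.003% in si-CLEC5A. Replicate 1 thus lay nearest the knockdown. Among 1000 sets of genes matched on length, GC content and expression the middle median was -0.0586 and the 2.5th percentile -0.108. Genes alike in these 3 measures thus do not account for it. The length was the one implied by the 2 tables, which put the members at a median percentile of 31.8. An effect on the shortest transcripts therefore stays open. As a hypothesis, the knockdown may lower these mRNAs, but both lists lost their camera call with an estimated correlation (adjusted p = 0.618 and 0.583). Apart from that, a state shared by libraries within a group, such as culture density, cannot be told apart from the knockdown here and was not tested.

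A further hypothesis was that called chemokine and MMP genes fell as part of wider regions. The 29 other tested genes within 500 kb of them, of neither family, had a median log2 fold change of -0.223, below the 2.5th percentile (-0.14) of 10000 random sets matched on expression, and -0.163 with trends removed, below -0.1. This goes with regional change, and 21 of the 29 were negative. MTHFD2L on chromosome 4 had a log2 fold change of -0.979 (SE 0.192, edgeR adjusted p = 0.0569). With trends removed edgeR called 2 of the 29, MTHFD2L (adjusted p = 0.000297) and BIRC3 (0.0265). That fit called 967 of 16506 genes, so 2 of 29 is near the share over all genes and says little about the regions. Yet AREG, EREG and BIRC3 are also induced by inflammatory signals, and MMP12 and MMP13 had positive values inside 1 cluster. Without trend removal edgeR called 0 of the 29, which says little where only 47 of 16506 genes were called.

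Other splits of the 6 libraries number 10 with the real one, too few for a share under 0.05. With edgeR the real split called 47 genes, 16 of them at least 2-fold, where the highest of the other 9 splits called 0 of either kind. For gene lists the real split gave 8 and the highest other split also 8, that of si-NC replicates 1 and 2 with si-CLEC5A replicate 1 against the rest. As many calls as the real one came from 1 split for genes, 1 for 2-fold changes and 2 for lists.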
